A study of Mus musculus with 4 samples.

How the data were processed

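The libraries came from spleen and bone marrow of 10-week-old female BALB/c mice bearing CT26 tumours, sorted for viable CD3-negative and CD19-negative cells. Per the labels, 6-OHDA was injected at 100 mg/kg 4 days before the tumour and at 200 mg/kg 2 days before and on the day of implantation, 4 hours before it. The 200 mg/kg dose, or vehicle, was then repeated every 6 days. Mice received 500000 CT26 cells intradermally and organs were taken after 18 days. Per the labels, 12000 cells per library were loaded on 10x Chromium version 3 chemistry and sequenced on a HiSeq4000 to a target of 50000 reads per cell, with mm10 as the genome build. The deposited matrices hold UMI counts, whole numbers per gene and cell barcode, with no normalization found in the values. The deposited names call them filtered matrices, so cell calling was done before deposit, and neither the labels nor the files state the aligner or its version. The lowest barcode total was 502 and 501 UMIs in the spleen and 500 in both marrow libraries.

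Barcodes with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs passed: 5826 of 6625 (vehicle spleen), 5708 of 6955 (6-OHDA spleen), 5677 of 6288 (vehicle marrow) and 6315 of 7160 (6-OHDA marrow). Likely doublets were removed per library with a simulated-doublet score, 2 simulated doublets per cell, at a share of 0.8% per 1000 barcodes, which took 272, 261, 258 and 319 cells. The 22416 kept cells had median UMI counts of 4952.5 and 7196 in spleen and 7506 and 7338.5 in marrow. Counts were scaled to 10000 per cell and log-transformed. The 4 libraries were clustered together without batch correction from 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1.0, which gave 40 clusters. The deposited data hold no cell annotation. A cluster took the name of the marker list with the highest score among 21 fixed lists if at least 3 markers were over 2-fold. A cluster stayed unnamed if its median UMI count, times 3, was under that of the library with most of its cells and its 10 leading genes held no marker of its list. This left 1 cluster unnamed, led by Klrc2 and with NK as its best list, with 64 vehicle and 31 6-OHDA spleen cells. The neutrophil-like clusters were led by genes such as Elane and Prtn3 (progenitor), Ltf and Camp (immature) and Retnlg or Il1b (mature), monocyte-like clusters by Fn1 and F13a1 or by Ace, NK-like clusters by Prf1, Eomes or the proliferation gene Top2a, and erythroid-like clusters by Car1, Gypa or Hba-a1.

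Each class share has an exact (Clopper-Pearson) 95% binomial interval and each difference of shares a Newcombe 95% interval. For expression, UMIs were summed over the cells of a class per library and given as CPM, that is, scaled to the same total for each sum. Sums carry exact Poisson intervals. The log2 ratio uses CPM + 1, and its interval is the exact conditional binomial interval of the ratio of the UMI sums without that pseudocount. Sums weigh deep cells more than shallow ones. Values within a class are given where both libraries hold at least 100 of its cells. The median log2 ratio of each fixed gene list is set beside 10000 random lists of as many genes matched on mean CPM, as a description of these libraries. The cell type markers, 28 gene lists with 434 genes, the filters and the comparisons were fixed before the data were examined. Of the 31053 genes in the files, 2 list genes had no match by symbol.

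Named genes had at least 100 UMIs over the 2 sums and at least 50 CPM in 1 of them. Mitochondrially encoded, ribosomal protein, haemoglobin and immunoglobulin genes were left out, as were genes with over 5 times the CPM in another class of at least 100 cells (possible free RNA). The rest were ranked by the bound nearer 0 of the interval of the log2 ratio. The rule takes 8 genes per direction in neutrophil-like cells and 4 in monocyte- and macrophage-like cells. It adds up to 4 members per described list, the 2 of highest mean CPM and the 2 of largest ratio, and Adrb2, Arg1, Nos2, S100a8, S100a9, Cd274, Il1b, Mki67 and the haemoglobin and immunoglobulin genes wherever measured. Genes named for neutrophil stages and for NK-like cells lie outside that rule. Coordinates are from GENCODE M21 for GRCm38 (mm10), in which 149 of 149 identifiers of named genes were found.

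The steps were tested on simulated data drawn from the neutrophil-like sums, with 200 genes changed by known folds among 2140 (spleen), 1970 (marrow) and 2053 genes (spleen against marrow). The interval held the true value for 95.5%, 94.2% and 95.3% of unchanged genes. For genes changed 1.5-fold, 2-fold and 4-fold it held the true fold for 97.0%, 94.0% and 95.5% in spleen and for 97.0%, 92.5% and 92.4% in marrow. Of 400 random lists per comparison, 6.25%, 5.0% and 6.25% lay outside the central 95%, and the interval of a share difference held the true value in 94.7%, 95.0% and 94.15% of draws. These simulations hold counting error only.

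Alternatives dropped the UMI, gene and mitochondrial limits with likely doublets still removed (6274, 6568, 5972 and 6750 cells; all barcodes kept, for short), used a stricter filter (1000 UMIs, 500 genes, 5% mitochondrial), kept doublets, used resolutions of 0.5 and 2.0, clustered each organ alone, left erythroid-like cells out of the denominator, scaled by median ratio or by a total without haemoglobin, immunoglobulin, S100a8 and S100a9, took the mean over cells of each cell's CPM, thinned cells to 1000 UMIs, used a pseudocount of 10, and used a minimum of 10 CPM or none. A further pair was chosen after seeing the data: mature neutrophil-like cells alone, and the monocyte-like class without its deepest cluster led by Ace. Classes with under 100 cells in a library got shares but no ratios or list medians, and CPM of single genes in them serves only to judge a class or background. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.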

Results

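Single cells sorted from the spleen and bone marrow of BALB/c mice carrying a CT26 colon carcinoma were profiled by droplet RNA sequencing. The sort kept viable cells without CD3 and CD19, which leaves out most T and B cells. The mice received vehicle or 6-hydroxydopamine (6-OHDA), a toxin taken up by noradrenergic terminals that destroys sympathetic nerves, and were killed 18 days after the tumour cells were implanted. There were 4 libraries, 1 for each organ and treatment, so no group has a replicate, no p-value can be given, and mouse-to-mouse differences cannot be separated from treatment. The labels do not say whether a library pooled several mice. The vehicle and 6-OHDA spleen libraries held 6625 and 6955 barcodes with 51357273 and 66902339 UMIs, and the marrow libraries 6288 and 7160 barcodes with 65666386 and 80448759 UMIs. After filtering, 5554 and 5447 spleen cells and 5419 and 5996 marrow cells were kept. Brackets give 95% intervals, which cover counting error only. Class names ending in "-like" come from marker genes, and shares are shares of the kept cells of a library, not numbers of cells per organ.

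The first question was whether the make-up of the tumour-bearing spleen differed after chemical denervation. Neutrophil-like cells and monocyte- and macrophage-like cells had higher shares, and natural killer (NK) cells a lower share, in the 6-OHDA spleen. Neutrophil-like cells, the class that would hold polymorphonuclear myeloid-derived suppressor cells (MDSC), made up 16.6% (903 cells; 15.6 to 17.6) in the 6-OHDA library and 12.1% (671 cells; 11.2 to 12.97) in the vehicle library. That difference was 4.50 percentage points (3.19 to 5.81). The share of monocyte- and macrophage-like cells was 21.6% against 16.9%, a difference of 4.68 points (3.21 to 6.16). NK-like cells made up 22.7% (1234 cells) against 34.7% (1930 cells), a difference of -12.1 points (-13.8 to -10.4). Of the NK-like clusters only cluster 1, with Prf1 and Klrg1 among its leading genes, was lower, at 9.27% against 24.4%. NK-like clusters 3 and 29 were higher.

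Within the spleen neutrophil-like cells, young stages took a larger part. Immature neutrophil-like cells, named from secondary granule genes such as Ltf, Camp and Ngp, made up 7.20% of the 6-OHDA spleen library (392 cells) and 2.21% of the vehicle library (123 cells), a difference of 4.98 points (4.20 to 5.78). Neutrophil progenitor-like cells, named from primary granule genes such as Mpo and Elane, made up 1.32% (72 cells) against 0.288% (16 cells). Mature neutrophil-like cells made up 8.06% against 9.58%, a difference of -1.52 points (-2.58 to -0.46). Of the neutrophil-like cells, 48.6% were mature in the 6-OHDA library and 79.3% in the vehicle library.

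Other spleen classes were smaller. Erythroid-like cells made up 5.65% (308 cells) in the 6-OHDA library and 3.66% (203 cells) in the vehicle library, a difference of 1.999 points (1.21 to 2.79). Conventional dendritic 1-like cells, the cross-presenting dendritic subset marked by Xcr1 and Clec9a, made up 4.06% against 2.48%, a difference of 1.57 points (0.91 to 2.25). Macrophage-like cells, marked by C1qa and the red pulp regulator Spic, made up 0.661% (36 cells) against 1.58% (88 cells). The intervals of the differences held 0 for T-like, basophil or mast-like, conventional dendritic 2-like and plasmacytoid dendritic-like cells. Within the conventional dendritic 2-like class, cluster 9 was lower (5.67% against 7.44%) and cluster 19 higher (3.93% against 3.17%). Barcodes over the mitochondrial limit made up 17.1% of the 6-OHDA and 11.8% of the vehicle spleen barcodes, so the limit left out more of the 6-OHDA library. With the stricter cell filter the difference in neutrophil-like share was 9.92 points, and without the UMI, gene and mitochondrial limits the difference in monocyte- and macrophage-like share was 3.12 points.

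**Figure D1:**
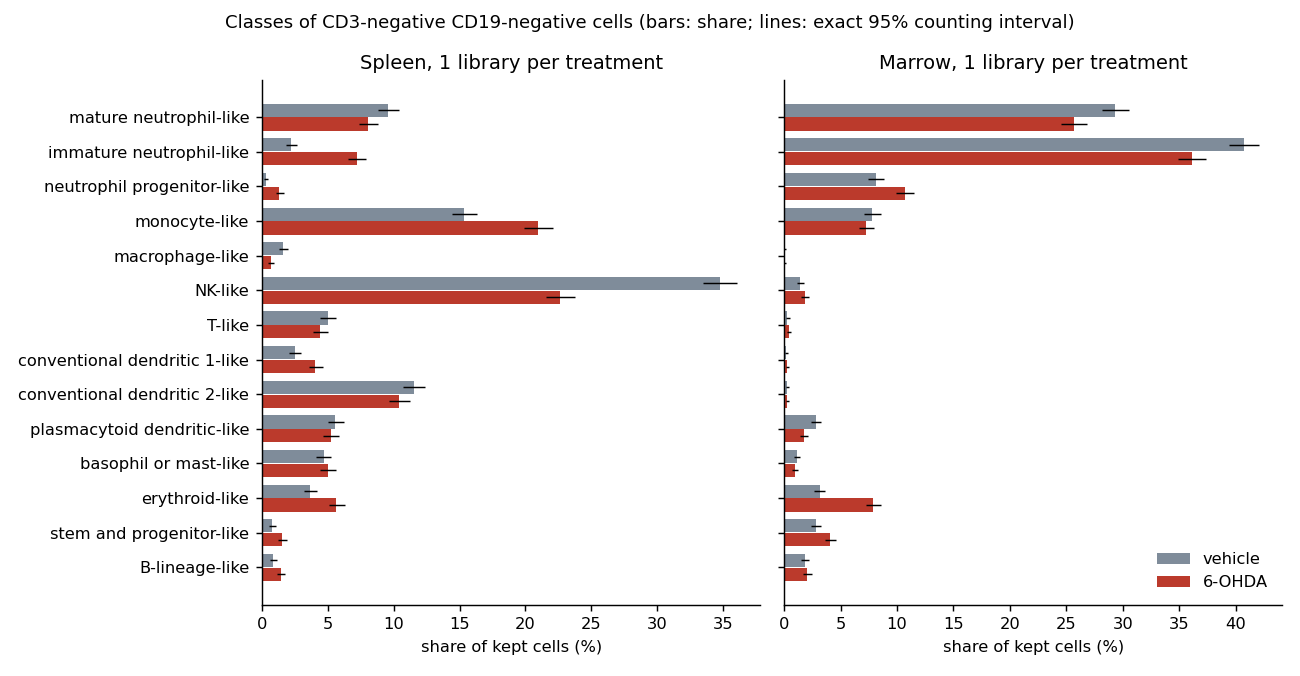
Share of kept cells (percent, with exact 95% binomial intervals) of cell classes in the vehicle and 6-OHDA libraries of spleen and marrow. Neutrophil stages, monocyte-like and macrophage-like cells are drawn separately. Plasma-like, megakaryocyte or platelet-like and unnamed cells are not drawn. NK-like cells are at 34.7% and 22.7% of the spleen libraries, and immature neutrophil-like cells at 40.7% and 36.1% of the marrow libraries.

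The second question was whether neutrophil-like cells of the spleen held other transcripts after 6-OHDA. In the sum over all stages, genes of the type I interferon response were lower. All 22 measured members of the list had lower CPM in the 6-OHDA library, 18 of them by at least 1.5-fold. Their median log2 ratio was -1.58. The central 95% of random lists of like abundance ran from -0.23 to 0.31. Ifit1, which binds foreign RNA, was at 10.5 CPM against 66.2 in vehicle (log2 -2.54; -3.06 to -2.26). Isg15, a ubiquitin-like interferon-induced modifier, was at 56.3 against 237 (log2 -2.06; -2.26 to -1.89), the antiviral enzyme gene Rsad2 at 25.5 against 117 and Rtp4 at 42.7 against 213. Ifit3b (6.84 against 56.2), Slfn5 (20.8 against 103) and Ifi27l2a (141 against 649) are interferon-induced too. Ifit1 (ENSMUSG00000034459) lies on chromosome 19 at 34640871 to 34650009 in mm10. The reads of Ifit3 and Ifit3b are uncertain, since these are near-identical copies. Gm13822 (22.1 against 108) was lower too.

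The difference in interferon-response genes was smaller but present among mature neutrophil-like cells alone, an alternative added after the stages were seen to differ. There the list median was -0.90 (random lists -0.28 to 0.08), with 21 of 22 members lower, 15 of them by at least 1.5-fold. In cluster 5 alone, which held 499 of 532 mature cells in vehicle and 351 of 439 after 6-OHDA, it was -0.63 (random lists -0.14 to 0.20). Summed over the list, immature neutrophil-like cells were near level, at 784 CPM (757 to 812) against 846 (800 to 894) in vehicle. Mature cells were at 3234 against 5024. Over the mature cells Ifit3 was at 13.7 against 97.3 CPM, Ifit1 at 71.9 against 202 and Isg15 at 384 against 712.

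**Figure D2:**
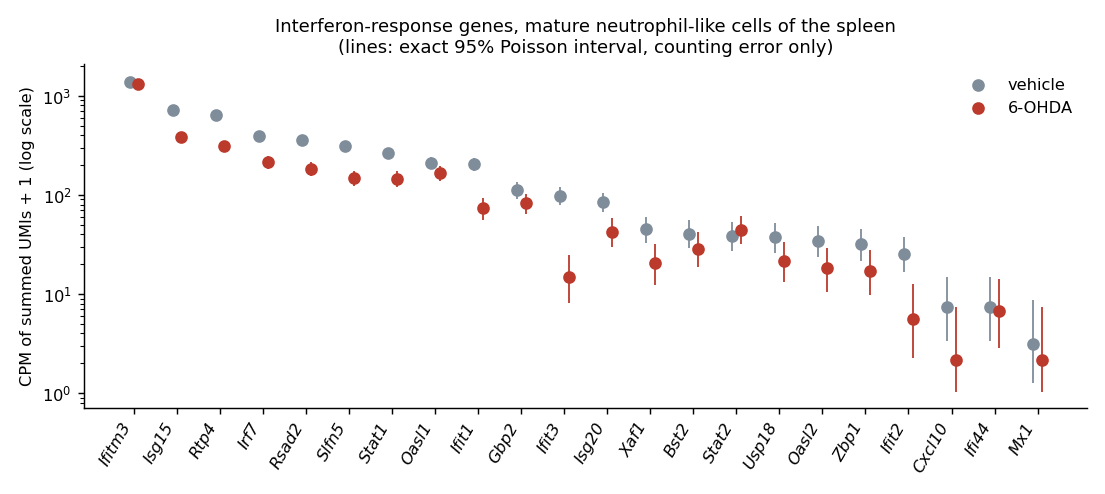
CPM + 1 (log axis) of the 22 genes of the type I interferon response list in mature neutrophil-like cells of the vehicle and 6-OHDA spleen libraries, with exact 95% Poisson intervals. The 6-OHDA value is lower for 21 of the 22 genes, with Isg15 at 384 against 712 CPM.

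Inflammatory and maturation genes were lower as well in the sum over all spleen neutrophil-like cells. The list of inflammatory cytokines and NF-kB targets had a median of -0.95 (random lists -0.27 to 0.39), with 14 of 15 measured members lower, 12 by at least 1.5-fold. Il1b (ENSMUSG00000027398, chromosome 2 at 129364570 to 129371139), the gene of interleukin-1 beta, was at 433 against 1617 CPM (log2 -1.90; -1.97 to -1.84), the receptor antagonist gene Il1rn at 43.7 against 111, and Zfp36, whose product degrades cytokine mRNA, at 199 against 396. The neutrophil maturation list had a median of -1.03 (random lists -0.37 to 0.36) with all 15 members lower. It includes Msrb1 at 935 against 2053 CPM and Retnlg at 2112 against 2488. Among mature cells alone the inflammatory median was 0.01, Zfp36 had a log2 ratio of 0.13 and Retnlg of 1.07, while Il1b was at 3400 against 4982 CPM (log2 -0.55).

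Most MDSC-associated genes were lower in the same sum. The list median was -0.60 (random lists -0.17 to 0.27), with 20 of 27 measured members lower, 16 by at least 1.5-fold. Wfdc17, which encodes a secreted protease inhibitor-like protein, was at 71.6 against 232 CPM and Cd274, the gene of PD-L1, at 5.56 against 19.3. The alarmin genes S100a8 and S100a9, the most abundant transcripts of the class, were near level with log2 ratios of 0.06 and -0.04, the second turning to 0.21 in mature cells and to 0.24 in the mean over cells. Arg1 and Nos2, whose enzymes consume arginine in suppressor cells, had 1 UMI each in the 6-OHDA library and 0 in vehicle, too few for a comparison. Among mature cells the list median was 0.06, with 15 members higher and 12 lower, including Cybb, the NADPH oxidase subunit gene, at 574 against 291 CPM.

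Genes of dividing granulocyte precursors were higher in the sum over all neutrophil-like cells of the 6-OHDA spleen. The primary granule list shares Mpo, Elane, Prtn3, Ctsg and Ms4a3 with the markers that name progenitor-like cells. It is therefore not separate from their higher share, and random lists were not matched for stage. The primary granule list had a median of 0.68 (random lists -0.46 to 0.39) with 9 of 10 members higher: the protease genes Prtn3 and Elane were at 2451 against 1332 CPM (log2 0.88; 0.83 to 0.93) and 1927 against 1145 (log2 0.75), and Prss57 at 74.5 against 41.4. All 27 cell cycle genes were higher, 17 by at least 1.5-fold, with a median of 0.64 (random lists -0.26 to 0.25) that was 0.26 in mature cells alone. Mki67 was at 190 against 122 CPM (log2 0.63; 0.46 to 0.80), the kinase gene Cdk1 at 130 against 72.1 and Rrm2, of ribonucleotide reductase, at 212 against 119. The linker histone genes Hist1h1b (94.0 against 38.3 CPM) and Hist1h1e (59.0 against 23.5), the endoplasmic reticulum stress factor gene Manf (192 against 82.5), the mitochondrial ribosomal gene Mrpl12 (76.6 against 28.6), Ppp1r14b (107 against 51.1) and the nuclear transport GTPase gene Ran (543 against 289) were higher too. Spata7 was at 66.7 against 20.4 CPM, of whose vehicle UMIs 1 cell gave 35.6%. Its log2 ratio of 1.66 turned to -0.46 under the stricter cell filter.

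Secondary and tertiary granule genes differed little in the sum over all stages, with a median of -0.02. Among mature cells this list had a median of 0.62 (random lists -0.26 to 0.03) with 14 of 15 members higher. Camp (ENSMUSG00000038357, chromosome 9 at 109847379 to 109849617), the gene of the antimicrobial peptide cathelicidin, was at 4351 against 1484 CPM there (log2 1.55), Ifitm6 at 1461 against 565 and Ly6g, the neutrophil surface marker, at 859 against 365. These 3 genes were chosen after the values were seen. The mature cells were not made up alike: clusters 0 and 10, deeper than cluster 5 and led by Retnlg or Olfm4, held 33 of 532 in vehicle and 88 of 439 after 6-OHDA. Adrb2 (ENSMUSG00000045730, chromosome 18 at 62177816 to 62179959), the gene of the beta-2 adrenergic receptor, was at 35.5 against 104 CPM over all stages (log2 -1.52; -1.80 to -1.30) and at 202 against 295 in mature cells.

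The clusters of the spleen neutrophil-like cells had other proportions in the vehicle and 6-OHDA libraries. Cluster 5, a mature cluster led by Il1b, Csf3r, Gm13822 and Dusp1, held 74.4% of them in vehicle and 38.9% after 6-OHDA. Sums over cells follow the deep immature cells: mature cells gave 934844 of the 2898536 UMIs of the vehicle neutrophil-like sum. After 6-OHDA they gave 875648 of 7020781. A gene held mainly by mature cells would thus be lower in the sum with no change within a stage. The neutrophil-like cells had median UMI counts of 1655 in vehicle and 3791 after 6-OHDA. Genes of other classes were present at low levels, as free RNA would bring: the NK genes Gzma and Ccl5 were at 27.9 against 196 and 55.3 against 288 CPM. The haemoglobin gene Hbb-bs was at 446 against 75.6 CPM, with 60.4% of the 6-OHDA UMIs from 1 cell.

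**Figure D3:**
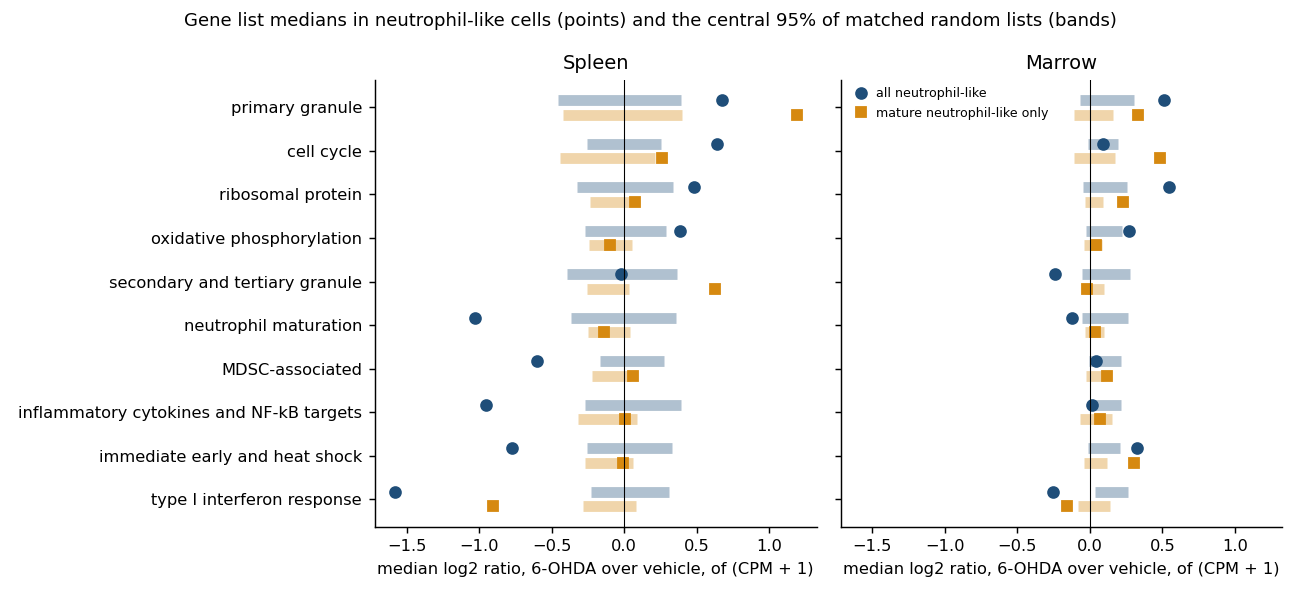
Median log2 ratio, 6-OHDA over vehicle, of 10 gene lists in all neutrophil-like cells (circles) and in mature cells alone (squares) of spleen and marrow, with the central 95% of random lists of like abundance (bands). In spleen the interferon list lies at -1.58 and at -0.90, and the MDSC-associated list at -0.60 and at 0.06.

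The third question was what the marrow of the same treatments held. Neutrophil-like cells made up 72.5% (4345 cells; 71.3 to 73.6) of the 6-OHDA and 78.2% (4237 cells; 77.1 to 79.3) of the vehicle library, a difference of -5.72 points (-7.30 to -4.14). Immature and mature neutrophil-like cells had lower shares, 36.1% against 40.7% and 25.7% against 29.4%, and progenitor-like cells a higher one, 10.7% against 8.10% (difference 2.59 points; 1.52 to 3.66). Erythroid-like cells made up 7.89% (473 cells) against 3.14% (170 cells), a difference of 4.75 points (3.93 to 5.58), and stem and progenitor-like cells 4.09% against 2.82%. Without the erythroid-like cells in the denominator, the difference in neutrophil-like share was -2.05 points. The intervals held 0 for the differences in the monocyte- and macrophage-like share, -0.52 points (-1.50 to 0.45), and in the NK-like share, 0.40 points (-0.07 to 0.86). Plasmacytoid dendritic-like cells made up 1.75% against 2.82%.

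In the sum over all marrow neutrophil-like cells, genes of early granulocytes were higher and genes of later granules lower after 6-OHDA. The primary granule list shares Mpo, Elane, Prtn3, Ctsg and Ms4a3 with the markers that name progenitor-like cells. Those cells gave 13707026 of 36677775 UMIs after 6-OHDA and 9641863 of 36660092 in vehicle. The list is therefore not separate from their higher share, and random lists were not matched for stage. The primary granule list had a median of 0.51 (random lists -0.07 to 0.30) with 9 of 10 members higher. Elane was at 3960 against 2711 CPM (log2 0.55), Prtn3 at 3812 against 2634, the protease gene Ctsg at 1089 against 662 (log2 0.72; 0.69 to 0.74) and Cst7 at 125 against 74.0. All 15 secondary and tertiary granule genes were lower, none by 1.5-fold, with a median of -0.24 (random lists -0.06 to 0.28). The chitinase-like gene Chil3 was at 1772 against 2451 CPM (log2 -0.47; -0.48 to -0.45), lysozyme gene Lyz2 at 8334 against 11180 and lactoferrin gene Ltf at 6709 against 8762. Camp and Ngp were lower by -0.19 and -0.31, but higher by 0.0023 and 0.0076 in mature cells, and Camp by 0.0019 under the stricter filter. Chil1, Gpr27, Stk39, Lst1 and Olfm4 were the other genes with the largest lower ratios, from -0.54 for Chil1 to -0.40 for Olfm4.

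Among the genes with the largest higher ratios in marrow neutrophil-like cells, Mif, the gene of macrophage migration inhibitory factor, was at 214 against 113 CPM (log2 0.91; 0.86 to 0.97), the serine synthesis gene Phgdh at 68.3 against 37.4, the nucleolar gene Npm1 at 615 against 366, the cold-induced RNA-binding protein gene Rbm3 at 771 against 464 and the chaperone gene Hsp90ab1 at 864 against 520. The mitochondrial genes Slc25a4 (52.4 against 29.2 CPM) and C1qbp (121 against 69.6) were higher too. Mif and Npm1 have processed pseudogenes, so their counts are uncertain where reads were shared. Progenitor-like cells made up 14.8% of the class after 6-OHDA and 10.4% in vehicle.

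In the marrow sum over all stages, the type I interferon response list had a median of -0.25 (random lists 0.03 to 0.26), with 20 of 22 members lower and 1 by at least 1.5-fold. Ifitm3 was at 484 against 616 CPM and Stat1 at 47.6 against 52.4. The median ranged from -0.09 with a pseudocount of 10 to -0.36 over genes with at least 10 CPM. The MDSC-associated median was 0.04 (random lists -0.01 to 0.21), with 13 members higher and 12 lower, and it was -0.05 under median-ratio scaling, so its direction is not settled. In mature cells it was 0.12 in marrow and 0.06 in spleen. S100a8 and S100a9 had log2 ratios of -0.23 and -0.26, Il1b was at 44.0 against 54.0 CPM and Junb at 107 against 85.2. The inflammatory list had a median of 0.01 with 9 members higher and 9 lower, and -0.07 under median-ratio scaling. Adrb2 was at 30.05 against 31.4 CPM. Mki67 had a log2 ratio of 0.07, which turned to -0.02 under median-ratio scaling and to -0.03 with a total without haemoglobin, immunoglobulin, S100a8 and S100a9.

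Log2 ratios of neutrophil-like cells in spleen and marrow were positively correlated across 2490 genes with at least 50 CPM in a library, with Pearson r 0.59 (0.58 to 0.60) and Spearman rho 0.68 (0.67 to 0.69). Genes are not independent replicates. Among mature cells alone r was 0.20, and 0.18 under the stricter cell filter.

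Monocyte- and macrophage-like cells of the 6-OHDA spleen were low in macrophage genes. The complement genes C1qa (26.4 against 152 CPM), C1qb (19.8 against 127; log2 -2.62; -2.88 to -2.49) and C1qc (17.1 against 109), the adhesion gene Vcam1 (27.4 against 177), the iron exporter gene Slc40a1 (47.9 against 140) and Spic (27.0 against 62.3) were lower. The iron and haem recycling list had a median of -0.54 (random lists -0.15 to 0.06) with 12 of 14 members lower, and the complement and phagocytosis list -0.21 (random lists -0.15 to 0.05) with 12 of 17 lower. These are genes of the macrophage-like cells, which made up 9.35% of the class in vehicle and 3.06% after 6-OHDA. Vcan, a gene of classical monocytes, was higher at 51.4 against 16.6 CPM (log2 1.57), the collagenase gene Mmp8 at 233 against 131, Wfdc17 at 1015 against 651, and BC100530, of the stefin A family whose copies can share reads, at 89.0 against 26.1. The interferon list had a median of -0.26 (random lists -0.12 to 0.04) with 20 of 22 lower. The MDSC-associated median was 0.22 (random lists -0.12 to 0.05), but 0.11 without the deepest cluster led by Ace, whose cells may include doublets. Genes of neutrophils were also higher in this class: Camp was at 4740 against 1867 CPM, Ngp at 4115 against 1604, S100a8 at 20995 against 9192 and S100a9 at 20474 against 9424. Mmp8 and BC100530 are leading genes of neutrophil-like clusters too. NK-like cells of the 6-OHDA spleen held 574 CPM of S100a8 and 119 of Camp, so free RNA at that level is too little to account for these values. The deepest cluster led by Ace made up 8.23% of the class after 6-OHDA and 2.98% in vehicle. Its part in these neutrophil genes is not given here, and neutrophils or doublets elsewhere in the class were not tested.

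In marrow monocyte- and macrophage-like cells, genes of MHC class II presentation were higher after 6-OHDA. All 9 had higher CPM, with a median of 0.70 (random lists -0.10 to 0.11). H2-Eb1 was at 63.3 against 5.51 CPM (log2 3.30; 3.05 to 4.03), H2-Aa at 135 against 24.9 and H2-Ab1 at 68.4 against 12.2. Few cells carried them: 23 of 440 cells had H2-Eb1 UMIs in the 6-OHDA and 9 of 426 in the vehicle library. The heat shock gene Hspa1a was at 93.5 against 19.2 CPM in this class. The fractalkine receptor gene Cx3cr1 was lower at 51.2 against 89.2, as were Spata7 (25.0 against 50.4) and Gm1673 (29.8 against 51.4). The basophil protease gene Prss34 was at 0.941 against 106 CPM, with 98.0% of the vehicle UMIs from 1 cell. The MDSC-associated and interferon lists had medians of 0.04 and 0.04. Genes of neutrophils were lower in this class: S100a8 was at 1824 against 3796 CPM, S100a9 at 1466 against 3609, Camp at 169 against 1134 and Ngp at 151 against 916. Elane was near level at 933 against 900. The deepest cluster led by Ace held 5 cells of this class in the vehicle and 0 in the 6-OHDA marrow library. Without it S100a8 was near level, so its lower value rested on that cluster. S100a9, Camp and Ngp without it are not given here. Neutrophils or doublets elsewhere in the class were not tested.

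Spleen NK-like cells held more cell cycle and less effector transcripts after 6-OHDA. Of 27 cell cycle genes, 26 were higher, with a median of 0.63 (random lists -0.13 to 0.05): Mki67 was at 215 against 116 CPM (log2 0.88; 0.77 to 1.01), Cenpf at 78.3 against 38.5 and Ube2c at 144 against 74.2. The cytotoxicity list had a median of -0.31 (random lists -0.13 to 0.08) with 15 of 20 members lower. The chemokine genes Ccl4 and Ccl5 were at 284 against 594 and 13510 against 20954 CPM, granzyme gene Gzma at 10156 against 13313, and Klrg1, a receptor of late effector cells, at 121 against 246. The retention receptor gene Cxcr4 was at 163 against 83.3 CPM, and S1pr5 (ENSMUSG00000045087, chromosome 9 at 21242912 to 21248443), a receptor used by NK cells to leave tissues, at 61.8 against 141. Cma1 (172 against 383) and Gpx8 (19.5 against 51.0) were lower too. Cluster 1 held 70.3% of the NK-like cells in vehicle and cluster 3 held 53.7% after 6-OHDA; Cma1, S1pr5, Klrg1, Gzma and Ccl5 are among the leading genes of cluster 1. Cluster 29, with Cenpf and Mki67 among its leading genes, held 5.35% of the NK-like cells after 6-OHDA and 2.33% in vehicle. The 4 genes in each direction for NK-like cells lie outside the rule for named genes, and were chosen by the same ranking after the values were seen. The interferon list did not differ from random lists in NK-like cells, with a median of -0.02 (random lists -0.17 to 0.11). Haemoglobin genes, named as signs of free RNA, were higher in NK-like cells after 6-OHDA. Hbb-bs was at 843 against 166 CPM and Hba-a1 at 194 against 62.8. Other spleen classes of at least 100 cells went both ways for Hbb-bs. It was lower in monocyte- and macrophage-like (892 against 2425), conventional dendritic 1-like (42.6 against 105), plasmacytoid dendritic-like, erythroid-like and basophil or mast-like cells. It was higher in T-like (141 against 92.8), conventional dendritic 2-like (122 against 87.4) and neutrophil-like cells. The NK-like values are not read as a general rise of free RNA, and how many cells gave them is not given.

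The last comparison set spleen against marrow in vehicle mice. Of the neutrophil-like cells, 79.3% were mature in spleen and 37.6% in marrow, a difference of 41.7 points (38.2 to 45.0), and 18.3% against 52.1% were immature. Spleen neutrophil-like cells were rich in inflammatory and interferon-induced transcripts: Il1b was at 1617 against 54.0 CPM (log2 4.88; 4.83 to 4.98), the cytokine signalling inhibitor gene Socs3 at 102 against 3.71, Wfdc17 at 232 against 14.98, the prothrombinase gene Fgl2 at 434 against 29.98, Steap4 at 131 against 4.88 and Ifit3b at 56.2 against 3.11. Cd244 (58.0 against 1.61 CPM) and Prr5l (58.3 against 1.88) were higher too. All 22 interferon-response genes were higher in spleen, with a median of 1.98 (random lists -0.16 to 0.30). The MDSC-associated list had a median of 1.20 with 18 of 24 members higher, the inflammatory list 1.30 with 13 of 17 and the maturation list 1.33 with 12 of 15. The primary granule genes were lower, with a median of -0.80 and 9 of 10 lower, among them Elane (1145 against 2711 CPM), Prtn3 (1332 against 2634), Prss57 (41.4 against 87.0) and Ms4a3 (218 against 411). This list shares markers with progenitor-like cells, which made up 2.38% of the spleen and 10.4% of the marrow class. Gpr27, Olfm4, Retnlg and Mmp8 were lower too, Gpr27 by 12.4 against 53.2 CPM. In the mature cells alone, the interferon median was 2.09 and the MDSC-associated median 1.02, where random lists ran from 0.16 to 0.84 and from 0.18 to 0.81. The mature cells of the 2 organs lay in different proportions of clusters: cluster 5 held 499 of 532 in spleen and 172 of 1591 in marrow, where clusters 0 and 10 held 1047 and 372. In the 6-OHDA pair, 48.6% of spleen and 35.4% of marrow neutrophil-like cells were mature. Over all stages of that pair, the interferon and MDSC-associated medians were 0.59 and 0.28, beside 1.98 and 1.20 in the vehicle pair.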

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

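Of the tests below, mixing of marrow cells judged by expression and a few cells with very high counts were planned before their results were seen. The tests of dilution, the mitochondrial limit, barcode swapping, mixing judged by mature cells, the stage mix and free RNA were chosen after the result was seen.

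Several values are listed because the 6-OHDA and vehicle libraries differed in opposite directions in the 2 organs, and none of these organ differences was tested. The neutrophil-like share differed by 4.50 points in spleen and -5.72 in marrow, 10.2 points apart, and the immature neutrophil-like share by 4.98 and -4.62, 9.60 points apart. In neutrophil-like cells, spleen minus marrow medians were -0.93 for the cAMP response list (-0.67 and 0.25), -1.10 for immediate early and heat shock genes (-0.78 and 0.32) and -1.10 for glucocorticoid response genes (-0.89 and 0.21). They were -1.63 for cytotoxicity genes (-1.43 and 0.20), -1.01 for iron and haem recycling (-0.93 and 0.09), -1.14 for complement and phagocytosis (-0.94 and 0.20) and -0.95 for immunoglobulin genes (-0.53 and 0.42). Marrow neutrophil-like ratios were shifted upward as a whole, with a median of 0.087 over genes with at least 50 CPM. The marrow iron and haem recycling value does not stand apart from that shift. The marrow complement and phagocytosis median was negative over genes with at least 10 CPM, so its direction is not settled. All 18 measured cytotoxicity genes in spleen neutrophil-like cells are possible free RNA from other cells, and so are all 6 measured immunoglobulin genes in marrow. Igkc in neutrophil-like cells was at 79.1 against 104 CPM in spleen, near its level in NK-like cells (138 against 123), and at 5.48 against 0.464 in marrow, where 3 and 0 plasma-like cells were found. The immunoglobulin values are therefore not read as expression of neutrophils. The spleen sums come from a class that was 79.3% mature in vehicle and 48.6% after 6-OHDA, and in mature cells alone the immediate early and heat shock median was -0.011 in spleen and 0.31 in marrow. In monocyte- and macrophage-like cells the MHC class II presentation list differed by -0.80 (-0.09 and 0.70).

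The NK-like share was lower in the 6-OHDA spleen, 22.7% against 34.7%. Dilution by more myeloid, erythroid and stem cells was argued against: outside those classes the NK-like share still differed by -10.7 points (-13.1 to -8.31), 41.5% against 52.2%. Loss of NK-like cells to the mitochondrial limit was argued against too, since without the UMI, gene and mitochondrial limits, with likely doublets still left out, the share of clusters with NK as best list differed by -11.3 points (-12.9 to -9.72). A difference between mice, sorts or handling stays open with 1 library per group, as does an effect of the treatment, and neither was tested.

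Immature and progenitor neutrophil-like cells were more frequent in the 6-OHDA spleen. Barcode swapping from the marrow libraries was argued against, as 2 of these 464 cells (0.43%; 0.052 to 1.55) had a barcode that a marrow library holds. Marrow cells mixed into the sample would also bring mature cells of the mostly-marrow clusters 0 and 10: the excess of these was 55.6 cells where 175 were needed, 31.8% (19.2 to 47.0), which argues against mixing as the whole cause but not against some. Judged by expression, mixing and spleen origin cannot be told apart, because only 5 genes met the condition where 20 were needed (median log2 ratio 2.55). Release of marrow cells, growth in the spleen and a difference between mice stay open and were not tested.

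Interferon-response genes were lower in neutrophil-like cells of the 6-OHDA spleen, with a median of -1.58. More young cells in the class are not the whole cause, since the median was -0.90 in mature cells alone (random lists -0.28 to 0.08), though it is nearer 0 there and was -0.63 in cluster 5, the main mature cluster (random lists -0.14 to 0.20). A few very high vehicle cells are argued against by a median of -0.88 (random lists -0.30 to 0.11) after the highest 5% of mature cells in each library were left out. Free RNA in the vehicle suspension was judged by NK-like cells, where the median was -0.025 with 13 of 22 genes lower. This cannot decide it, since vehicle NK-like cells were deeper than neutrophil-like cells (median 3345.5 against 1655 UMIs). Other clusters also went both ways, with -0.43 in T-like cluster 14 (18 of 22 lower) and 0.20 in NK-like cluster 1 (8 of 22 lower). Free RNA stays open. A treatment effect and a difference between mice, such as their interferon exposure or time to sorting, stay open, untested.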

How the results depend on the processing

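The main shares, gene list medians and correlation had 150 values under alternatives: 112 lay within the interval of the reported value, 36 lay outside it (13 larger in size, 23 smaller) and 2 had the opposite sign to a reported interval without 0. By sign alone, 135 of the 150 had the sign of the reported value; the rest include values of results whose interval holds 0. The other results had 2277 values: 1474 within, 777 outside (267 larger in size, 510 smaller) and 26 with the opposite sign to an interval without 0. By sign alone, 2181 of the 2277 had the reported sign. Mature neutrophil-like cells alone, and the monocyte class without its deepest Ace-led cluster, were alternatives chosen after seeing the data. All barcodes kept means without the UMI, gene and mitochondrial limits, with called doublets still removed. Causes of the differences below were not tested, except where the construction of the alternative shows them. No paired analysis was possible because the labels link no spleen library to a marrow library of the same mouse, and each group has 1 library.

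For shares, the spleen difference in neutrophil-like cells was 9.92 points under the stricter filter (4.50 reported), and that in monocyte- and macrophage-like cells 3.12 with all barcodes kept (4.68 reported). The marrow neutrophil-like difference was -2.05 without erythroid-like cells in the denominator, which shows that part of the reported -5.72 comes from the higher erythroid-like share. The vehicle spleen against marrow difference in mature share was 53.8 points at resolution 0.5 (41.7 reported). The spleen B-lineage-like difference turned to -0.16 with each organ clustered alone (0.57 under the main setting).

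In spleen neutrophil-like cells the MDSC-associated median (-0.60 reported) was -0.38 in the mean over cells, -0.95 over genes with at least 10 CPM and 0.061 in mature cells alone. The type I interferon median (-1.58 reported) was -1.29 in the mean over cells, -0.93 with a pseudocount of 10 and -0.90 in mature cells alone. The inflammatory median (-0.95 reported) was -0.71 under the stricter filter, -0.77 with each organ clustered alone, -0.57 in the mean over cells, -0.54 in cells thinned to 1000 UMIs, -0.60 with a pseudocount of 10 and 0.0074 in mature cells alone. Restricting to mature cells leaves out the younger stages, but the mature clusters also differed in their parts, with cluster 5 holding 499 of 532 vehicle and 351 of 439 6-OHDA cells.

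Other spleen neutrophil-like values changed sign. Under the stricter filter Spata7 was -0.46 and S100a9 0.10. S100a9 was 0.041 with each organ clustered alone, 0.24 in the mean over cells, 0.22 in thinned cells and 0.21 in mature cells. Retnlg was 0.37 in the mean over cells, 0.33 in thinned cells and 1.07 in mature cells. In mature cells Mmp9 was 0.11, Adam8 0.32, Zfp36 0.13, Hmgb2 -0.088 and the oxidative phosphorylation median -0.10.

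In marrow neutrophil-like cells the MDSC-associated median (0.04 reported) was -0.048 under median-ratio scaling, -0.053 with the total without haemoglobin, immunoglobulin, S100a8 and S100a9, -0.065 in thinned cells, -0.028 over genes with at least 10 CPM and 0.12 in mature cells. The interferon median (-0.25 reported) was -0.14 under the stricter filter, -0.34 and -0.35 under those scalings, -0.086 with a pseudocount of 10, -0.36 over genes with at least 10 CPM and -0.16 in mature cells. The inflammatory median was -0.073 under median-ratio scaling (0.01 reported). The maturation median turned to 0.060 under the stricter filter and 0.034 in mature cells. Over genes with at least 10 CPM the haemoglobin and erythrocyte median was -0.18 and the complement and phagocytosis median -0.27. Mki67 was -0.022 and -0.028 under the scalings named above, Camp 0.0019 under the stricter filter and 0.0023 in mature cells, and Ngp 0.0076 in mature cells. In marrow monocyte- and macrophage-like cells S100a8 (-1.06 reported) was 0.20 with each organ clustered alone and 0.018 without the Ace-led cluster.

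The correlation of spleen and marrow log2 ratios in neutrophil-like cells (0.59 reported) was 0.57 with all barcodes kept, 0.18 under the stricter filter, 0.64 with doublets kept, 0.55 at resolution 2.0, 0.47 in the mean over cells, 0.40 in thinned cells, 0.61 with a pseudocount of 10, 0.53 over 7033 genes with at least 10 CPM, 0.37 over 17030 genes with no minimum and 0.20 in mature cells.

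Some alternatives gave no value. NK-like cells had none under the stricter filter or with each organ clustered alone (12 spleen results and 1 marrow result each). With each organ clustered alone, 81 marrow neutrophil-like results and 1 spleen stem and progenitor-like result had none. Plasma-like shares with all barcodes kept and plasmacytoid dendritic-like shares at resolution 2.0 had none in either organ. A class with no cells in a library could still hold up to 0.0664% or 0.0677% of the spleen and 0.0680% or 0.0615% of the marrow libraries. Thinning left out 56 and 65 spleen and 114 and 152 marrow neutrophil-like cells with fewer than 1000 UMIs.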

Other observations

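Interferon-response genes were not lower in every cell type of the 6-OHDA spleen. The median log2 ratio of the list was -1.14 in a basophil-like cluster (28), with all 21 measured genes lower, but 0.04 in the other basophil-like cluster (26) with 9 of 20 lower. It was -0.63 in the mature neutrophil cluster 5 with 19 of 22 lower, -0.43 in the T-like cluster 14 and -0.38 in the monocyte-like cluster 4. It was 0.16 in the monocyte-like cluster 11 (random lists -0.12 to 0.09) and 0.20 in the NK-like cluster 1. Dendritic clusters went both ways: 0.20 in the conventional dendritic 2-like cluster 19, but -0.22 in the larger cluster 9 of that class with 18 of 22 lower (random lists -0.10 to 0.20). It was -0.27 in the plasmacytoid cluster 8 with 15 of 21 lower, and -0.19 in the conventional dendritic 1-like cluster 22 with 15 of 22 lower. Summed over the list, mature neutrophil-like cells held 3234 CPM after 6-OHDA and 5024 in vehicle, basophil or mast-like cells 983 and 1646, and conventional dendritic 2-like cells 3092 and 2702. Neutrophil genes were also higher in the basophil or mast-like class, S100a8 at 43931 against 24318 CPM and Camp at 7881 against 2152. How far neutrophil RNA or doublets enter the interferon values of its clusters was not tested.

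Stem and progenitor-like cells had higher shares in the 6-OHDA libraries of both organs, 1.56% against 0.774% in spleen (difference 0.79 points; 0.39 to 1.20) and 4.09% against 2.82% in marrow (1.26 points; 0.59 to 1.93). The class named megakaryocyte or platelet-like held 17 against 8 cells in spleen, a difference of 0.17 points (-0.014 to 0.37) that holds 0, and 37 against 5 in marrow. At resolutions 0.5 and 2.0, 44 of its 67 cells were named erythroid-like, and Hbb-bs was at 13533 CPM in its 6-OHDA marrow cells, so the class is mixed and no statement on megakaryocytes is made. A mast-like cluster led by Mcpt1, Mcpt4 and Cpa3 held 42 cells of the 6-OHDA and 12 of the vehicle spleen, and 3 and 2 in marrow.

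Most immediate early and heat shock genes were higher in marrow after 6-OHDA. In marrow neutrophil-like cells 18 of 21 had higher CPM after 6-OHDA, with a median of 0.32 (random lists -0.02 to 0.21). In marrow monocyte- and macrophage-like cells 20 of 21 were higher, Hspa1a among them at 93.5 against 19.2 CPM. In spleen neutrophil-like cells the median was -0.78 over all stages and -0.011 in mature cells, and the difference between organs was not tested. These genes also respond to tissue handling, and the labels give no time from death to sorting. The median mitochondrial share of marrow barcodes was 2.43% after 6-OHDA and 1.59% in vehicle. Barcodes over the mitochondrial limit made up 11.7% and 9.67%.

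Some values rest on few cells. The possible doublets of the deepest Ace-led cluster, with a median of 20014 UMIs, numbered 97 in the 6-OHDA and 28 in the vehicle spleen. In marrow they numbered 0 and 5. An unnamed spleen cluster with a median of 929 UMIs and NK as best list held 31 and 64 cells. Adrb2 was lower in some classes and near level in others, and how many cells carried its UMIs is not given here. In spleen monocyte- and macrophage-like cells (1178 and 941 cells) Adrb2 was at 74.6 against 115 CPM, and in the marrow class at 15.9 against 22.0. In spleen NK-like cells it was at 9.82 against 18.8, in T-like cells at 7.43 against 15.1 and in basophil or mast-like cells at 35.7 against 56.4. It was near level in spleen conventional dendritic 2-like (32.9 against 31.3) and conventional dendritic 1-like cells (42.6 against 38.5). The same held for plasmacytoid dendritic-like (30.4 against 29.5) and erythroid-like cells (8.66 against 8.41).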
